A study of Homo sapiens with 12 samples.

How the data were processed

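Gene expression was measured in 12 samples of the human cell line 293T/17 on Illumina bead arrays. Per the labels, 6 samples came from cells with a short hairpin RNA knockdown of SPAG4 and 6 from control cells named wildtype, and 3 samples of each were given DMSO vehicle or camptothecin (2 µM, 48 hours). Per the labels' protocols, RNA was extracted with Trizol and purified on RNeasy columns, checked on a Bioanalyzer, and 100 ng was labelled with biotin using the Ambion TotalPrep kit. Probe signals were summarised in BeadStudio, per the submitters' processing notes, and the software version is not given in the sources used here.

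The deposited table of non-normalized values gives an intensity per probe and array, the mean bead signal on a linear scale, with no background subtraction or normalization visible in the values. Per the file headers, each intensity is followed by a detection p-value, which in the values runs in steps of 1 in 759 and compares the probe with negative control beads of the same array. A deposited matrix of processed values is on a log2 scale and equals the quantile-normalized log2 intensity without background correction, with a largest difference of 5.00e-09. It was used only as an alternative.

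Of 48797 probes, 28094 had 1 gene symbol, 13 several and 20690 none. The number of probes with a detection p under 0.01 was 8509 ± 1135 (SD, n = 3) for control vehicle, 11059 ± 192 for control camptothecin, 11750 ± 138 for knockdown vehicle and 12458 ± 314 for knockdown camptothecin arrays. The 95th percentile of signal was 214 ± 61.3, 302 ± 53.0, 572 ± 138 and 571 ± 130 in the same order. Pearson's r of normalized values was 0.945 to 0.990 between arrays of a group and 0.857 to 0.965 between groups.

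Signals were background-corrected by normexp with parameters inferred from the detection p-values, with an offset of 16, quantile-normalized and log2-transformed (neqc of limma 3.58.1 in R 4.3.3). Probes detected at p under 0.01 on all 3 arrays of at least 1 group were kept (11882, of which 10374 had 1 symbol), and the probe with the highest mean signal stood for each gene, giving 8254 genes, of which 1814 had over 1 such probe. The SPAG4 probe failed this filter and was added to a separate fit of the same genes, which gave its values and adjusted p. A linear model with 4 group means was fitted to all 12 arrays with lmFit and eBayes, and p-values were adjusted by Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05. The 5 comparisons were knockdown against control under vehicle and under camptothecin, camptothecin against vehicle in control and in knockdown cells, and the interaction, the difference between the camptothecin effects in knockdown and control cells. The median standard error of a log2 fold change was 0.19, and 0.27 for the interaction.

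Before the data were examined, 23 pathway lists and 5 cell type lists with 844 genes were written down, of which 6 genes had no current symbol. The pathway lists were p53 target genes, DNA damage checkpoint and repair, DNA topoisomerases, DNA replication, mitosis, histone genes, apoptosis, immediate early genes and AP-1, unfolded protein response and ATF4, heat shock proteins, NF-kappa-B and cytokines, interferon response, histocompatibility and antigen presentation, nuclear envelope genes with the LINC complex and lamina, centrosome, cilium and sperm flagellum, hypoxia and glycolysis, cholesterol biosynthesis, cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, oxidative stress and metallothioneins, RNA polymerase II elongation and splicing, and cell adhesion, cytoskeleton and matrix. The cell type lists were neuronal, kidney epithelial, fibroblast, blood cell and testis germ cell markers. With 0 testis markers measured, 27 lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list and with fry, which tests a list against no change and not against the other genes. Counts adjusted over the list alone use the p-values of its members only.

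Genes were named by a rule fixed beforehand: SPAG4, the 10 highest and 10 lowest log2 fold changes past the threshold with no overlap between groups (5 and 5 for camptothecin in knockdown cells and for the interaction, the latter without the overlap condition), and from each list described the 3 largest changes past the threshold, or the 2 smallest p-values where fewer than 2 members passed. Genes with placeholder symbols were passed over. Members were named only for lists past the threshold in that comparison and for the nuclear envelope list, a choice made after a first run of the alternatives. Where a gene was undetected on all arrays of 1 group, a lower bound of the fold change is given. The bound takes, per array of the dim group, the higher of the lowest detected signal and the gene's own signal.

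Alternatives were no background correction, normexp with an offset of 50, median scaling, the deposited processed values, no detection filter, detection on all arrays, all probes, only the arrays compared, the replicate number as a block, array weights, a robust variance trend, and leaving out each array. Median scaling centred each array on the median of all its probes, of which 15.3% to 26.2% were detected. Its centre is therefore the signal of undetected probes, and it does not remove a difference in brightness of detected probes. A slide block was not run, since the files show no slide. Median scaling over probes detected on all arrays and array brightness (log2 of the 95th percentile of signal) as a covariate were added after seeing the data. Expected overlaps assume independent lists, and 100 simulations of unchanged groups gave the covariance that shared arrays produce. Gene lengths and chromosomes came from a RefSeq gene table, since the array files name no genome build.

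The fit was tested on simulated data with 200 changed genes among 8254. Of genes changed by 1 on the log2 scale it recovered 72% for knockdown under vehicle, 59% for knockdown under camptothecin, 68% and 69% for camptothecin in control and knockdown cells and 34% for the interaction. Of genes changed by 2 it recovered 98%, 97%, 96%, 97% and 77%, with 12, 6, 12, 8 and 5 unchanged genes called. The list test recovered a shift of 0.5 of the mitosis list and called 0 other lists. The simulated genes were independent and had the same spread in all groups. These rates therefore do not cover correlated genes or arrays that differ in brightness or spread. Figures were drawn with matplotlib 3.10.9.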

Results

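Gene expression was measured on 12 Illumina bead arrays in 293T/17 cells, an established human embryonic kidney line that carries the SV40 large T antigen. The arrays form 4 groups of 3. Cells with a short hairpin RNA against SPAG4 and control cells were each given either the DMSO vehicle or camptothecin, a topoisomerase I poison that traps the enzyme on DNA, at 2 µM for 48 hours. Each array carried 48797 probes, and 8254 named genes entered the tests. The arrays differed in the number of probes detected. The number of probes detected above the negative control beads was 8509 ± 1135 (SD, n = 3) in control cells with vehicle and 11059 ± 192 in control cells with camptothecin. It was 11750 ± 138 in knockdown cells with vehicle and 12458 ± 314 in knockdown cells with camptothecin. Unless stated otherwise, log2 fold changes are given with their standard error from the fit, with 3 arrays in each group. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They name the control cells wildtype and do not say whether these carried a control hairpin, so a difference between knockdown and control cells is not by itself an effect of SPAG4. Where a probe was detected on only some arrays of a group, the number is given, and the size of its change is uncertain.

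SPAG4, also called SUN4, encodes a SUN domain protein of the nuclear envelope and is known for its expression in spermatids. Its only probe lay near background and was detected on 0 of 3 arrays in both vehicle groups. It was detected on 1 of 3 arrays in control cells with camptothecin and on 2 of 3 in knockdown cells with camptothecin. The probe failed the detection filter, so it was fitted beside the 8254 genes, and its p-values were adjusted together with theirs. Between knockdown and control cells its log2 fold change was 0.01 with vehicle (95% confidence interval -0.32 to 0.34, adjusted p = 0.973) and -0.10 with camptothecin (-0.43 to 0.24, adjusted p = 0.745). The knockdown was therefore not measurable at this probe, and the hairpin's position relative to the probe is not given in the sources used here. With camptothecin its normalized log2 signal was 4.92 to 5.47 on 6 arrays, and with vehicle 4.41 to 4.61 on the other 6, higher with camptothecin in control (adjusted p = 0.00295) and knockdown cells (adjusted p = 0.00940). The size is uncertain, since the vehicle signals were not above background.

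Comparing knockdown with control cells under vehicle gives the difference between the cell states without the drug. Knockdown cells had less HSPA1A, the inducible HSP70 chaperone, by at least 149-fold (adjusted p = 6.74e-12). Its normalized log2 signal was 12.33 ± 0.19 (SD, n = 3) in control cells and at background on all 3 knockdown arrays. The near-identical HSPA1B differed only by -0.59 ± 0.12 (adjusted p = 0.00942) and was detected on all 3 knockdown arrays, so the HSPA1A probe did not take up HSPA1B RNA measurably there. The HSPA1B probe can take up HSPA1A RNA, which leaves the HSPA1B value uncertain. The cell cycle gene CCND1, which encodes cyclin D1, was 8.99-fold lower (adjusted p = 9.73e-07) and SNAI2, which encodes the transcription factor Slug, 8.54-fold lower (adjusted p = 2.23e-06). The heat shock gene HSPA6 fell 4.77-fold and CRABP2, a retinoic acid binding protein, 4.56-fold. The other genes with the lowest log2 fold changes were TRIM16L at -3.12 ± 0.56, SNHG10 at -2.24 ± 0.48, the cyclophilin PPID at -1.95 ± 0.37, the gasdermin GSDMA at -1.85 ± 0.38 and the amino acid transporter SLC7A2 at -1.84 ± 0.20. Of these, SNHG10 was detected on 1 of 3 knockdown vehicle arrays and HSPA6, TRIM16L and GSDMA on 2 of 3.

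The protease inhibitor SPINT2 was at least 5.51-fold higher in knockdown cells under vehicle (adjusted p = 4.10e-05). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was at least 3.23-fold higher (adjusted p = 4.31e-05), and the enolase ENO2 at least 1.98-fold higher (adjusted p = 2.71e-06). The axonal transport motor KIF1A rose 7.81-fold and the neuronal pentraxin NPTX1 5.13-fold, although 2 other NPTX1 probes gave 0.11 and 0.47 on the log2 scale. SHISA2 was 6.44-fold higher and LRRC26 at least 2.60-fold higher. SPRY2, an inhibitor of receptor tyrosine kinase signalling, rose 4.47-fold, the glucocorticoid-inducible TSC22D3 3.84-fold and SLAIN1 3.72-fold. KIF1A and SPRY2 were detected on 1 of 3 control vehicle arrays and SHISA2 and NPTX1 on 2 of 3. In all, 1339 of 8254 genes passed the limma test at an adjusted p of 0.05, 973 higher and 366 lower, of which 303 and 74 differed over 2-fold. The number called was 683 without knockdown vehicle replicate 1, 747 without knockdown vehicle replicate 2, 544 with only the 6 arrays compared and 18 with array brightness as a covariate, among which HSPA1A, CCND1, SPINT2 and CDKN1A stayed past the threshold (adjusted p = 1.07e-07, 0.00560, 0.0328 and 0.0258). The split of calls followed the scaling, with 7282 higher and 8 lower after median scaling, and 427 and 2478 after median scaling over detected probes. Median scaling centres each array on undetected probes, and the median log2 fold change of all genes was 1.43 after it. Among the 4504 genes detected on all arrays the split was 443 and 418. That filter removed 665 higher calls, 662 of them undetected on a control vehicle array, so this split decides nothing.

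Of 27 gene lists fixed beforehand, camera called 6 between knockdown and control cells under vehicle. Among histone genes, 10 of 19 measured members rose, 0 fell and 9 did not pass the gene test (list adjusted p = 0.00105). Their median log2 fold change lay 0.45 above that of all genes, but -0.46 from it after median scaling, where the list's direction turned (adjusted p = 0.822). The call was also lost after median scaling over detected probes (adjusted p = 0.431). The linker histone H1-2 had a log2 fold change of 1.78 ± 0.22 and H2BC5 of 1.65 ± 0.18, each detected on 1 of 3 control vehicle arrays, and H4C14 was at least 1.42-fold higher. Among 18 cholesterol biosynthesis genes 6 fell and 2 rose, with the median -0.63 from that of all genes (list adjusted p = 0.00105), and the call was lost after both median scalings (adjusted p = 0.803 and 0.258). DHCR7, the last enzyme of the pathway, fell 2.16-fold, while the sterol reductase TM7SF2 rose by 1.52 ± 0.36 and the phosphomevalonate kinase PMVK by 1.06 ± 0.25 on the log2 scale, detected on 2 of 3 and 1 of 3 control vehicle arrays. With an estimated correlation, but without median scaling, both lists passed (adjusted p = 0.0389 for each). Among genes detected on all arrays, cholesterol genes were the only list called (adjusted p = 0.000185), and the histone call was lost with 6 members left (adjusted p = 0.0764). Adjusted over the list alone, the members higher and lower were 12 and 0 for histones and 2 and 10 for cholesterol genes. Beside these groups, the 95th percentile of signal was 572 ± 138 (SD, n = 3) on knockdown vehicle arrays and 214 ± 61.3 on control vehicle arrays.

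The calls of the other 4 lists were lost with an estimated correlation. After median scaling, and after median scaling over detected probes, the adjusted p was 0.00360 and 0.368 for heat shock proteins and 0.341 and 0.00102 for ribosomal proteins. It was 0.560 and 0.934 for ribosome biogenesis and 0.351 and 0.232 for apoptosis, so 1 of the 6 calls stayed under each. Among genes detected on all arrays these 4 calls were lost as well, with adjusted p of 0.791, 0.305, 0.215 and 0.603 in the same order. The ribosome biogenesis call was lost without a detection filter too (adjusted p = 0.107) and without control vehicle replicate 1, and the apoptosis call without control vehicle replicate 2 or knockdown vehicle replicate 3. Heat shock proteins were lower as a list (adjusted p = 0.0168, and 0.130 as adjusted p with an estimated correlation), with 3 of 15 members lower, 1 higher and 11 not past the gene test, led by HSPA1A, HSPA6 and HSPA1B. The list's median lay -0.21 from the median of all genes and its mean -0.80 from their mean, with HSPA1A at -7.88 in the fit. The filter for detection on all arrays removes HSPA1A, and how far the call rests on this gene was not tested. Among 63 cytosolic ribosomal proteins 5 were lower and 58 did not pass (list adjusted p = 0.00260, with an estimated correlation adjusted p = 0.290). RPL14 was 2.00-fold, RPL23 1.74-fold and RPL34 1.57-fold lower, while second probes of RPL14 and RPL34 gave 0.11 and 0.23 on the log2 scale (adjusted p = 0.716 and 0.388). Among 30 ribosome biogenesis genes 3 were lower and 1 higher (list adjusted p = 0.0141, with an estimated correlation adjusted p = 0.290), and this direction turned after median scaling. The nucleolar NOLC1 was at -0.73 ± 0.14 and NHP2 at -0.45 ± 0.13, against 1.06 ± 0.32 for the RNA polymerase I factor RRN3, detected on 1 of 3 control vehicle arrays. Among 25 apoptosis genes 6 rose and 1 fell (list adjusted p = 0.0312, with an estimated correlation adjusted p = 0.338). The pro-apoptotic PMAIP1 rose 2.75-fold and the mitochondrial protease HTRA2, detected on 2 of 3 control vehicle arrays, 1.87-fold, whereas the death receptor gene TNFRSF10B fell 1.74-fold. TNFRSF10B and SLC7A2 lie in a stretch of chromosome 8 in which 33 of 71 genes were lower in knockdown cells under vehicle. Adjusted over the list alone, the members higher and lower were 2 and 3 for heat shock proteins, 0 and 4 for ribosomal proteins, 1 and 3 for ribosome biogenesis and 9 and 1 for apoptosis.

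SPAG4 belongs to the family of SUN proteins, which pair with KASH proteins across the nuclear envelope. Of 21 measured genes of this complex, the lamina and the nuclear envelope, 1 was higher and 1 lower in knockdown cells under vehicle (list adjusted p = 0.996). The nuclear pore gene NUP107 was at 0.55 ± 0.14 and the inner membrane gene TMEM43 at -0.58 ± 0.13. With camptothecin 0 were higher and 2 lower (list adjusted p = 0.843), the lamin B receptor LBR at -0.57 ± 0.12 and TMPO at -0.51 ± 0.14. Of 27 centrosome, cilium and sperm flagellum genes, 4 were higher and 0 lower under vehicle (list adjusted p = 0.213). None of the 15 testis germ cell markers reached the tests. Of 9 measured neuronal markers, 4 were higher and 1 lower (list adjusted p = 0.0725), and of 23 p53 target genes 7 were higher and 2 lower (list adjusted p = 0.156), neither list passing the threshold. Among the 21 lists that did not pass, adjusted p values ranged from 0.0725 to 0.996.

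With camptothecin in both arms, knockdown cells again had less HSPA1A, at least 29.4-fold (adjusted p = 4.58e-10), and more SPINT2, 10.6-fold (adjusted p = 8.42e-05). CCND1 was 4.16-fold lower and CRABP2 4.92-fold lower. TRIM16L was at least 3.41-fold lower (adjusted p = 0.0263), MXRA8 at least 3.20-fold lower and DPYSL3 at least 2.92-fold lower. The interferon-inducible IFITM1 fell 4.29-fold, the deadenylase gene CNOT7 4.11-fold and the mitotic kinase gene PBK 3.71-fold, and the intermediate filament gene PRPH was at -1.85 ± 0.28 on the log2 scale. CNOT7 and PBK lie in the chromosome 8 stretch named above, where 38 of 71 genes were lower with camptothecin. Among the genes that rose, NAPRT, an enzyme of NAD synthesis, was at least 5.39-fold higher, the transcription factor gene FOXQ1 4.69-fold and SHISA2 4.28-fold higher. TCEAL3 was at least 3.03-fold higher, the interferon regulatory factor IRF7 at least 2.04-fold, and the zinc finger genes ZSCAN18 and ZNF35 at least 2.37-fold and 2.23-fold. The log2 fold change was 1.99 ± 0.25 for MIR503HG and 1.97 ± 0.19 for the enamel matrix gene AMBN, whose 2 other probes gave 0.69 and 1.16. FOXQ1 and MIR503HG were detected on 1 of 3 control camptothecin arrays. In all 736 genes passed the limma test, 371 higher and 365 lower, of which 76 and 95 differed over 2-fold. The count was 405 without control camptothecin replicate 2, 371 and 412 without knockdown camptothecin replicates 2 and 3, 1181 without control vehicle replicate 2, and 96 with array brightness as a covariate. The split was 5575 higher and 25 lower after median scaling, and 278 and 777 after median scaling over detected probes.

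Between knockdown and control cells under camptothecin camera called 9 lists, and all 9 calls were lost with an estimated correlation, as given here for each. Among genes detected on all arrays only DNA replication was called (adjusted p = 0.00864), and the adjusted p of the other 8 lists ranged from 0.0820 to 0.265. The unfolded protein response call was lost on leaving out any of 8 arrays, oxidative phosphorylation with any of 5 and cholesterol genes with any of 4. Histocompatibility genes lost theirs with either of 2 arrays and oxidative stress genes with 1. The number of lists was 5 without control camptothecin replicate 1 and 5 without knockdown camptothecin replicate 3. After median scaling, and after median scaling over detected probes, calls were lost for immediate early genes (adjusted p = 0.0798 and 0.0892), histocompatibility genes (0.163 and 0.0623) and cholesterol genes (0.516 and 0.238). After median scaling alone, those of oxidative phosphorylation (0.516) and oxidative stress genes (0.128) were lost too. Among 23 immediate early and AP-1 genes 5 rose and 0 fell (list adjusted p = 0.0104, with an estimated correlation adjusted p = 0.0955). They included the stress-induced ATF3 at 0.92 ± 0.16, the mRNA decay factor ZFP36, detected on 1 of 3 control camptothecin arrays, at 0.90 ± 0.15 and EGR1 at 0.79 ± 0.14. Among 35 DNA replication genes 5 rose and 0 fell (list adjusted p = 0.0114, with an estimated correlation adjusted p = 0.124), led by the origin recognition subunit ORC6 at 0.89 ± 0.17, thymidylate synthase TYMS at 0.87 ± 0.16 and cyclin E1, CCNE1, at 0.70 ± 0.17. Among 27 unfolded protein response and ATF4 genes 3 rose and 1 fell (list adjusted p = 0.0468, with an estimated correlation adjusted p = 0.198). STC2 was at 1.31 ± 0.19 and the transcription factor CEBPB at 0.66 ± 0.17, against -1.03 ± 0.18 for the disulfide isomerase PDIA6.

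The remaining 6 of these lists were lower in knockdown cells under camptothecin. Among 15 heat shock proteins 3 fell (list adjusted p = 0.00270, with an estimated correlation adjusted p = 0.0940): HSPA1A as above, HSPB1 at -0.63 ± 0.16 and HSP90AA1 at -0.42 ± 0.12. How far this call rests on HSPA1A, at -5.48 in the fit, was not tested. Among 12 histocompatibility and antigen presentation genes 2 fell (list adjusted p = 0.0253, with an estimated correlation adjusted p = 0.124), HLA-B at -0.95 ± 0.25 and the immunoproteasome subunit PSMB10 at -0.61 ± 0.12. Probes of HLA-B can take up RNA of other HLA class I genes. Among 18 cholesterol biosynthesis genes 3 fell (list adjusted p = 0.0371, with an estimated correlation adjusted p = 0.124), EBP at -0.83 ± 0.15, CYP51A1 at -0.76 ± 0.19 and DHCR7 at -0.70 ± 0.12. Among 63 ribosomal proteins 2 fell (list adjusted p = 0.00884, with an estimated correlation adjusted p = 0.198), RPL14 at -0.83 ± 0.18 and RPS21 at -0.51 ± 0.14. No single member passed among 13 oxidative stress and metallothionein genes (list adjusted p = 0.0325, with an estimated correlation adjusted p = 0.124) or 42 oxidative phosphorylation genes (list adjusted p = 0.0449, with an estimated correlation adjusted p = 0.191). The smallest p values there belonged to MT1F at -0.92 ± 0.28 and MT1X at -0.42 ± 0.16, and to NDUFB10 at -0.36 ± 0.11 and ATP5F1D at -0.35 ± 0.13. Adjusted over the list alone, the members higher and lower were 6 and 1 for immediate early genes, 5 and 0 for DNA replication, 7 and 1 for the unfolded protein response, 0 and 5 for heat shock proteins, 0 and 2 for histocompatibility genes, 0 and 3 for cholesterol genes, 0 and 1 for ribosomal proteins, and 0 and 0 for both remaining lists. Among the 18 lists that did not pass, adjusted p values ranged from 0.0945 to 0.843.

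**Figure D1:**
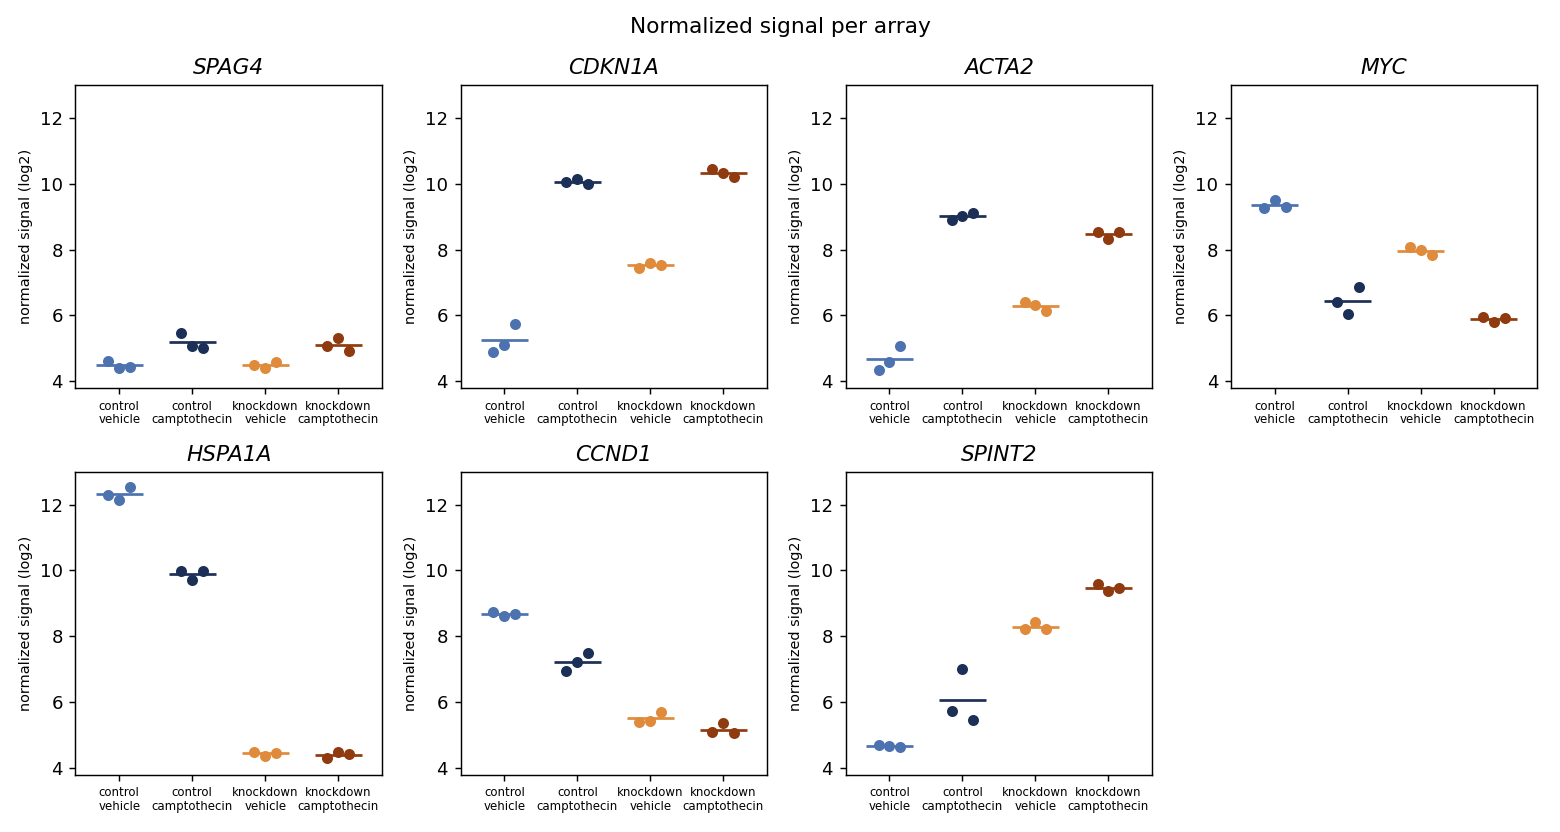
Normalized log2 signal (vertical axis) of 7 genes on each of the 12 arrays, by group (horizontal axis). Points are arrays and bars are means of 3 arrays; HSPA1A sits near the background level on all 6 knockdown arrays, and CDKN1A rises with camptothecin in both cell states.

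The effects of the knockdown under vehicle and under camptothecin share no arrays. They do share the same fit with its estimate of spread per gene. Knockdown arrays were also brighter in both, with a 95th percentile of signal of 572 against 214 and 571 against 302. The overlap can therefore exceed that of independent lists without a knockdown effect on the same genes. Of the genes called in both, 159 were higher in both, where independent lists would share 43.7, and 153 were lower in both, where independent lists would share 16.2. Another 8 genes were called in opposite directions. Pearson's r of the log2 fold changes was 0.504 across genes, which are not independent replicates. The number called in the same direction, 312, was 5216 after median scaling. It was 202 without control camptothecin replicate 2, 195 and 205 without knockdown vehicle replicates 1 and 2, and 190 and 193 without knockdown camptothecin replicates 2 and 3.

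Camptothecin against vehicle in control cells asks how cells without the knockdown respond to the drug. CDKN1A was at least 18.8-fold higher (adjusted p = 2.62e-08), the smooth muscle actin ACTA2 at least 9.02-fold and YPEL3 at least 12.8-fold higher. CGA, the shared subunit of glycoprotein hormones, was at least 7.53-fold higher, the hair keratin-associated KRTAP19-1 at least 4.74-fold, and the p53-inducible oxidoreductase TP53I3 at least 5.34-fold. The histone genes H2BC5, H1-2 and H2AC18 rose by 4.19 ± 0.18, 4.14 ± 0.22 and 3.70 ± 0.22 on the log2 scale, and TYMSOS, which overlaps the thymidylate synthase gene on the opposite strand, rose 17.7-fold. Histone genes have near-identical copies, so the value of a single copy is uncertain. MYC, the growth-promoting transcription factor, fell 7.56-fold (adjusted p = 6.69e-07). The lowest log2 fold changes belonged to CMSS1 at -3.32 ± 0.13 and BABAM2, a subunit of the BRCA1-A complex, at -3.18 ± 0.19. MTHFD1L of mitochondrial folate metabolism fell 7.90-fold, SUCLG2 of the citric acid cycle 7.66-fold, the carbonic anhydrase CA2 7.58-fold, and the mitochondrial phenylalanyl-tRNA synthetase FARS2 at least 4.07-fold. SND1 was at least 6.18-fold lower. WDR4, a tRNA methyltransferase subunit, was at -3.05 ± 0.21 and adenosine kinase, ADK, at -2.81 ± 0.28, while a second WDR4 probe gave -0.50 (adjusted p = 0.109) and 2 other ADK probes gave -0.76 and -0.55. SUCLG2, WDR4 and ADK were detected on 1 of 3 control camptothecin arrays and BABAM2 and MTHFD1L on 2 of 3, and H2BC5 and H1-2 on 1 of 3 control vehicle arrays. In all 3832 genes passed the limma test, 2271 higher and 1561 lower, of which 966 and 521 differed over 2-fold. The split was 2861 higher and 119 lower after median scaling, 1212 and 1991 after median scaling over detected probes, and 1098 and 1390 among 4504 genes detected on all arrays.

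Camera called 11 lists in control cells, and 4 of these calls held with an estimated correlation. Among 23 p53 target genes 15 rose, 0 fell and 8 did not pass, with the median 1.22 above that of all genes (list adjusted p = 2.26e-07, with an estimated correlation adjusted p = 0.00661). Besides CDKN1A and TP53I3, the secreted stress factor GDF15 was at least 2.87-fold higher. Among 19 histone genes 16 rose and 1 fell (list adjusted p = 1.39e-07, with an estimated correlation adjusted p = 0.00661). Among 30 ribosome biogenesis genes 22 fell and 1 rose, with the median -0.90 from that of all genes (list adjusted p = 1.65e-08, with an estimated correlation adjusted p = 0.0169). MYBBP1A was at least 2.78-fold lower, NOP16 2.64-fold lower and NHP2 2.52-fold lower. Among 23 immediate early and AP-1 genes 15 rose and 1 fell (list adjusted p = 0.00140, with an estimated correlation adjusted p = 0.0253). The transcription factor KLF4 was at least 1.92-fold higher and the matrix protein CCN1, detected on 1 of 3 vehicle arrays, 4.04-fold higher, while MYC, a member of the same list, was the gene that fell. These 4 directions held under each scaling, but among genes detected on all arrays the immediate early call was lost (7 members, adjusted p = 0.0756).

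The other 7 calls in control cells were lost with an estimated correlation. The call of DNA replication was lost after both median scalings too (adjusted p = 0.389 and 0.169), and that of apoptosis after median scaling (adjusted p = 0.0963) and without control vehicle replicate 2. Among genes detected on all arrays the calls of interferon response and mitosis stayed, with 2 of 10 and 37 of 39 members left. Those of histocompatibility genes (adjusted p = 0.681), apoptosis (0.0756), DNA replication (0.244) and kidney markers (0.155, 1 member) were lost, and 0 blood markers were left. Kidney and blood markers also lost their calls without a detection filter (adjusted p = 0.345 for each). Interferon response genes were higher (8 of 10, 0 lower, list adjusted p = 0.000549, with an estimated correlation adjusted p = 0.0637), with IFITM1 6.52-fold, IFI6 5.56-fold and IFI35 at least 1.79-fold. Histocompatibility and antigen presentation genes were higher (8 of 12, 1 lower, list adjusted p = 0.0227, with an estimated correlation adjusted p = 0.0865), with HLA-B 8.62-fold, HLA-F 3.73-fold and the peptide transporter TAP1 3.15-fold. Among 25 apoptosis genes 11 rose and 0 fell (list adjusted p = 0.0227, with an estimated correlation adjusted p = 0.247), including BAX at 1.39 ± 0.19, the death receptor TNFRSF10B at 1.35 ± 0.15 and BMF, which was undetected under vehicle and is given without a fold (adjusted p = 0.000146). Among 39 mitosis genes 16 rose and 1 fell (list adjusted p = 0.00671, with an estimated correlation adjusted p = 0.0808), with the kinesin KIF2C at 1.71 ± 0.18, the centrosomal kinase NEK2 at 1.42 ± 0.25 and the phosphatase CDC25B at 1.33 ± 0.11. Among 35 DNA replication genes 14 fell and 3 rose (list adjusted p = 0.0208, with an estimated correlation adjusted p = 0.134), with the DNA polymerase subunit POLA1 at least 1.97-fold lower, TYMS 2.47-fold and CDC45 1.84-fold lower. All 3 measured kidney epithelial markers rose (list adjusted p = 0.0218, with an estimated correlation adjusted p = 0.0865), the keratins KRT8 and KRT18 by 2.81 ± 0.35 and 1.09 ± 0.12, and EPCAM at least 1.78-fold. Both measured blood cell markers rose (list adjusted p = 0.0218, with an estimated correlation adjusted p = 0.141), the lysosomal CD68 at least 2.00-fold and the globin HBA2 3.02-fold. KRT8 was detected on 1 of 3 control vehicle arrays, and IFITM1, HLA-F, TAP1, POLA1 and HBA2 on 2 of 3.

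Adjusted over the list alone, the members higher and lower in control cells were 15 and 0 for p53 targets, 16 and 1 for histones, 1 and 23 for ribosome biogenesis, 16 and 1 for immediate early genes, 8 and 0 for interferon response, 8 and 1 for histocompatibility genes, 12 and 0 for apoptosis, 16 and 1 for mitosis, 3 and 14 for DNA replication, 3 and 0 for kidney markers and 2 and 0 for blood markers. The lists of RNA polymerase II elongation and splicing (6 higher, 13 lower, adjusted p = 0.0502), DNA damage checkpoint and repair (2 higher, 6 lower, adjusted p = 0.119) and DNA topoisomerases (2 higher, 0 lower of 6, adjusted p = 0.745) did not pass. Neither did hypoxia and glycolysis (10 higher, 12 lower, adjusted p = 0.495), cell adhesion, cytoskeleton and matrix (5 higher, 4 lower, adjusted p = 0.952), NF-kappa-B and cytokines (2 higher, 1 lower of 6, adjusted p = 0.559) or fibroblast markers (1 higher of 2 measured, adjusted p = 0.258). Among the 16 lists that did not pass, adjusted p values ranged from 0.0502 to 0.952.

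In knockdown cells, camptothecin raised AMBN at least 7.94-fold (adjusted p = 5.81e-07), YPEL3 10.7-fold, CGA at least 5.78-fold, H2BC5 7.92-fold and KRTAP19-1 7.72-fold. Another 2 AMBN probes rose by 1.00 and 1.98 on the log2 scale. Genes that fell were ADK at -3.46 ± 0.28, CMSS1 at -3.43 ± 0.13, MTHFD1L at -2.86 ± 0.22 and CA2 at -2.82 ± 0.18, and FAF1, a ubiquitin-binding protein, was at least 7.28-fold lower. The other ADK probes gave -1.27 and -1.13. KRTAP19-1 was detected on 2 of 3 knockdown vehicle arrays, ADK on 1 of 3 and MTHFD1L on 2 of 3 knockdown camptothecin arrays. In all 3169 genes passed the limma test, 1609 higher and 1560 lower, of which 567 and 452 differed over 2-fold, and 1946 passed after median scaling, 1123 higher and 823 lower. Among 4504 genes detected on all arrays, 1023 were higher and 1378 lower.

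Camera called 8 lists in knockdown cells, and 6 of them held with an estimated correlation. Among histone genes 18 of 19 rose and 1 fell (list adjusted p = 7.33e-09), and among p53 targets 16 of 23 rose and 0 fell (list adjusted p = 5.81e-08). CDKN1A rose 6.97-fold, TP53I3 6.83-fold and GDF15 at least 2.98-fold, while H1-2 rose 4.41-fold and H2AC18 4.09-fold. Among immediate early genes 17 of 23 rose and 1 fell (list adjusted p = 5.58e-07), with KLF4 at 2.32 ± 0.32, ATF3 at 2.08 ± 0.16 and MYC at -2.07 ± 0.18. Among ribosome biogenesis genes 18 of 30 fell and 1 rose (list adjusted p = 5.47e-06), with HEATR1 at -1.37 ± 0.19, NHP2 at -1.18 ± 0.13 and MYBBP1A at -1.13 ± 0.18. Of the interferon response genes 8 of 10 rose (list adjusted p = 6.23e-05), IFI6 3.74-fold, IFITM1 2.72-fold and IFI35 at least 2.29-fold. Of the mitosis genes 17 of 39 rose and 1 fell (list adjusted p = 0.000339), with CDC25B at 1.39 ± 0.11 and KIF2C at 1.09 ± 0.18 against DLGAP5 at -1.45 ± 0.15. The call of mitosis was lost after median scaling (adjusted p = 0.101) and that of kidney epithelial markers after median scaling over detected probes (adjusted p = 0.0576). The kidney call was also lost with no background correction (adjusted p = 0.0655), an offset of 50 (0.0634), no detection filter (0.134), genes detected on all arrays (0.537, 1 member) and on leaving out any of 8 arrays. The blood call was lost with no detection filter (adjusted p = 0.169), and 0 of its members were detected on all arrays. With an estimated correlation the calls of both remaining lists were lost, blood cell markers (adjusted p = 0.0131, with an estimated correlation adjusted p = 0.132) and kidney epithelial markers (adjusted p = 0.0499, with an estimated correlation adjusted p = 0.132). In those lists HBA2 was at 1.83 ± 0.22, CD68 at 1.39 ± 0.11, KRT8 at 1.68 ± 0.35, EPCAM at 1.67 ± 0.24 and KRT18 at 0.39 ± 0.12. KRT8 was detected on 1 of 3 and KLF4, IFITM1, EPCAM and HBA2 on 2 of 3 knockdown vehicle arrays, and MYBBP1A on 2 of 3 knockdown camptothecin arrays. Adjusted over the list alone, the members higher and lower were 18 and 1 for histones, 16 and 0 for p53 targets, 17 and 1 for immediate early genes, 1 and 19 for ribosome biogenesis, 9 and 0 for interferon response, 17 and 1 for mitosis, 3 and 0 for kidney markers and 2 and 0 for blood markers. Among the 19 lists that did not pass, adjusted p values ranged from 0.0957 to 0.949.

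**Figure D2:**
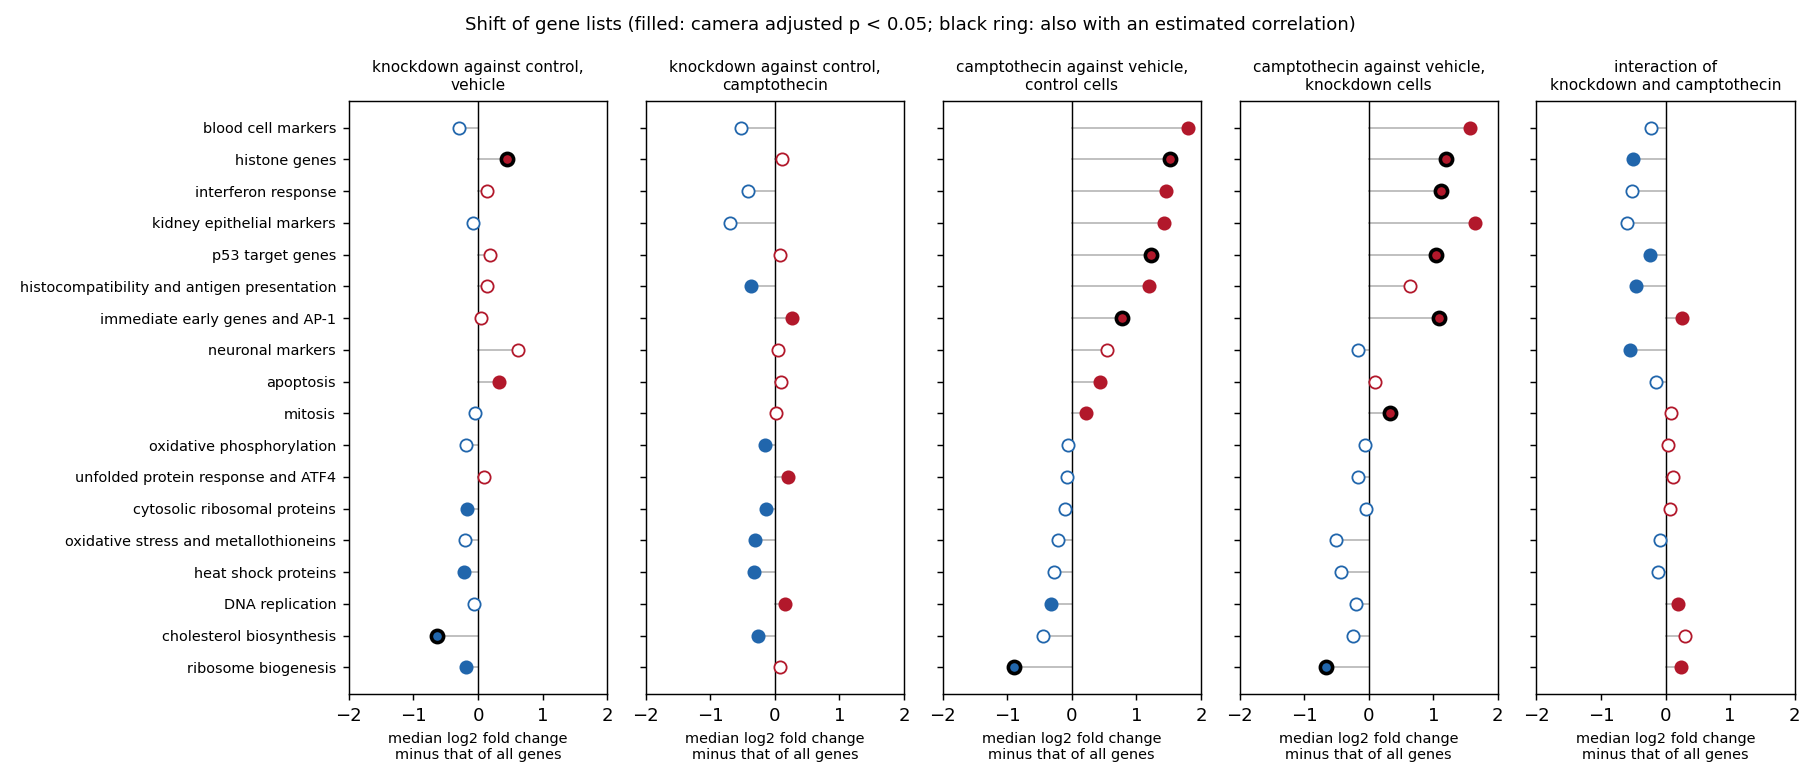
Median log2 fold change of each gene list minus that of all genes (horizontal axis), in each of the 5 comparisons, for lists called in at least 1 comparison (rows). Filled points passed camera and black rings mark calls that also held with an estimated correlation; p53 target genes lie 1.22 and 1.05 above all genes with camptothecin in control and knockdown cells.

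The responses of control and knockdown cells to camptothecin share no arrays. They share the estimate of spread per gene from the same fit, so their overlap too can exceed that of independent lists. Of the genes called in both, 1275 were higher in both, where independent lists would share 443, and 1166 were lower in both, where independent lists would share 295. Another 7 were called in opposite directions, and r of the log2 fold changes was 0.822 across genes. The number called in the same direction, 2441, was 969 after median scaling. The knockdown effect under vehicle and the camptothecin effect in control cells do share the control vehicle arrays. Their log2 fold changes had a covariance of 0.153, against 0.0296 in simulations of unchanged groups, and r of 0.408 against 0.501. The corresponding covariance with the camptothecin effect in knockdown cells was 0.0248, against -0.0295. The simulations used independent genes and 1 spread per gene for all groups, so a larger or common spread of the shared arrays is not covered. With 3 shared arrays the controls could not be split into parts of at least 2 arrays each.

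**Figure D3:**
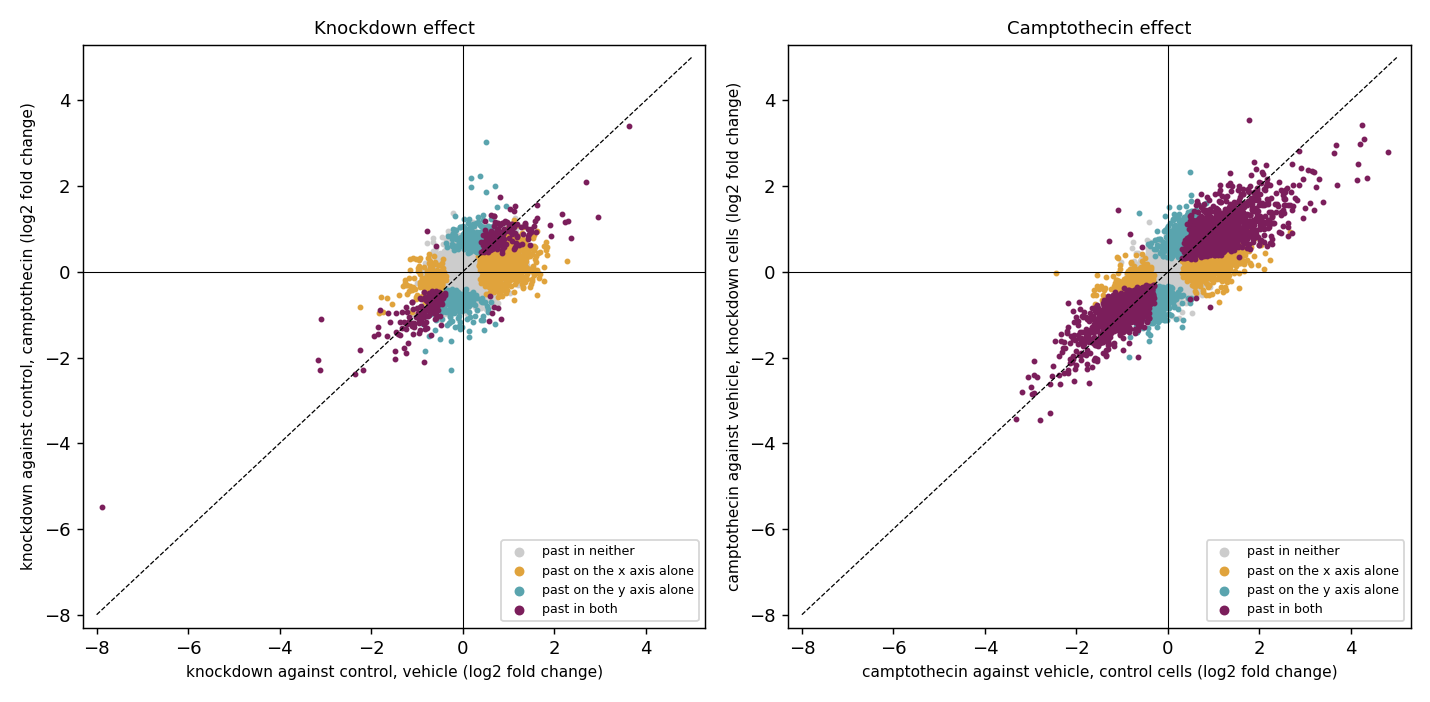
Log2 fold changes per gene in pairs of comparisons that share no arrays, with the dashed line marking equal change. Left, knockdown against control under vehicle (horizontal) and camptothecin (vertical), r = 0.504; right, camptothecin against vehicle in control (horizontal) and knockdown cells (vertical), r = 0.822; colours mark genes past an adjusted p of 0.05.

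The interaction asks whether camptothecin changed a gene differently in knockdown and control cells. CDKN1A rose less in knockdown cells, from 7.52 ± 0.08 to 10.32 ± 0.13 (log2 signal, SD, n = 3) against 5.25 ± 0.45 to 10.06 ± 0.07 in control cells, with an interaction of -2.01 ± 0.27 (adjusted p = 0.00778). It was below detection in control cells under vehicle. The interaction was -2.15 ± 0.25 for ACTA2 (adjusted p = 0.00500), -2.00 ± 0.30 for H1-2 (adjusted p = 0.0130) and -1.94 ± 0.39 for TEX19 (adjusted p = 0.0476). For MXRA8 it was -2.04 ± 0.22 (adjusted p = 0.00500), and among the 4 groups this gene was detected only in control cells with camptothecin. It was positive for NAPRT at 2.51 ± 0.43 (adjusted p = 0.0236), SNAI2 at 2.00 ± 0.25 (adjusted p = 0.00617), FOXQ1 at 1.85 ± 0.34 (adjusted p = 0.0326) and AMBN at 1.79 ± 0.27 (adjusted p = 0.0130). Several of these genes were partly below detection, which leaves the size of their interactions uncertain. ACTA2 was undetected on all control vehicle arrays and AMBN on all vehicle arrays. In control cells NAPRT was detected on 1 of 3 vehicle and 0 of 3 camptothecin arrays, and FOXQ1 on 0 of 3 and 1 of 3. FOXQ1 was detected on 1 of 3 knockdown vehicle arrays, and H1-2 and TEX19 on 1 of 3 control vehicle arrays. TEX19 was detected on 2 of 3 knockdown camptothecin arrays. The value for HSPA1A, 2.40 ± 0.19 (adjusted p = 0.000282), goes with its fall from 12.33 ± 0.19 to 9.89 ± 0.15 in control cells, as it was at background on all 6 knockdown arrays. In all 73 of 8254 genes passed the limma test, 15 higher and 58 lower, and 1206 had an unadjusted p under 0.05. The split was 90 higher and 21 lower after median scaling over detected probes, and the count was 24 after median scaling, 24 with brightness as a covariate and 24 among genes detected on all arrays. It rose to 277, 126 and 128 without control vehicle replicates 1, 2 and 3. It fell to 38 without control camptothecin replicate 2, to 15, 27 and 38 without knockdown vehicle replicates 1, 2 and 3, and to 25, 15 and 28 without knockdown camptothecin replicates 1, 2 and 3.

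Camera called 7 lists in the interaction, and 0 held with an estimated correlation. Immediate early genes alone stayed past the threshold under both median scalings, and the adjusted p of the other 6 ranged from 0.154 to 0.923 after median scaling and from 0.134 to 0.939 over detected probes. The p53 call was also lost with no background correction (adjusted p = 0.147), an offset of 50 (0.109), genes detected on all arrays (0.679) and on leaving out any of 9 arrays. Without a detection filter the calls of histones (adjusted p = 0.104) and neuronal markers (0.275) were lost. Histone genes were lower (3 of 19, list adjusted p = 0.00725, with an estimated correlation adjusted p = 0.0944), with H2AC18 at -1.67 ± 0.31 and H2BC12 at -0.95 ± 0.17 besides H1-2, but the direction turned under both median scalings. The p53 targets were lower (1 of 23, list adjusted p = 0.0492, with an estimated correlation adjusted p = 0.139), with PMAIP1 at -0.84 ± 0.18 (adjusted p = 0.0568) besides CDKN1A, and this direction turned as well. Histocompatibility genes were lower with 0 members past the gene test (list adjusted p = 0.00725, with an estimated correlation adjusted p = 0.0944), HLA-B at -1.50 ± 0.36 and HLA-C at -0.82 ± 0.22. Neuronal markers were lower (1 of 9, list adjusted p = 0.00725, with an estimated correlation adjusted p = 0.139), with ENO2 at -1.11 ± 0.19 and INA at -0.77 ± 0.21 (adjusted p = 0.108). HLA-C and ENO2 were undetected in control cells under vehicle. Immediate early genes (list adjusted p = 0.00602, with an estimated correlation adjusted p = 0.0944), ribosome biogenesis genes (list adjusted p = 0.00602, with an estimated correlation adjusted p = 0.139) and DNA replication genes (list adjusted p = 0.00725, with an estimated correlation adjusted p = 0.139) were higher with 0 members past the gene test, the last turning after median scaling. Their smallest p values belonged to ZFP36, undetected in both vehicle groups, at 0.80 ± 0.21 and MYC at 0.85 ± 0.26, POLR1C at 0.66 ± 0.19 and WDR12 at 0.53 ± 0.19, and TYMS at 0.69 ± 0.22 and RRM2 at 0.53 ± 0.18. Adjusted over the list alone, the members higher and lower were 1 and 8 for histones, 1 and 6 for p53 targets, 0 and 2 for histocompatibility genes, 0 and 4 for neuronal markers, and 0 and 0 for each of the last 3 lists. The nuclear envelope list did not pass (adjusted p = 0.992), with TMEM43 at 0.52 ± 0.18 and NUP107 at -0.42 ± 0.20. Among the 20 lists that did not pass, adjusted p values ranged from 0.120 to 0.992.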

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

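Camptothecin changed 73 genes differently in knockdown and control cells by the interaction test, a difference between groups. The 10 named genes were NAPRT (2.51), HSPA1A (2.40), SNAI2 (2.00), FOXQ1 (1.85), AMBN (1.79), ACTA2 (-2.15), MXRA8 (-2.04), CDKN1A (-2.01), H1-2 (-2.00) and TEX19 (-1.94), as log2 interactions. HSPA1A and MXRA8 were undetected in both knockdown groups, so their values reflect a change in control cells alone. ACTA2 was undetected in control cells under vehicle and AMBN in both vehicle groups. NAPRT and FOXQ1 were detected on at most 1 of 3 arrays in each control group, FOXQ1 also in knockdown cells under vehicle, and H1-2 and TEX19 on 1 of 3 control vehicle arrays. The size of these 6 interactions is uncertain. For CDKN1A, undetected in control cells under vehicle, the camptothecin effect was at least 18.8-fold in control cells against 6.97-fold in knockdown cells.

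Other splits of the arrays were counted for each number of genes called. For the interaction, 5 of 100 splits called at least as many genes as the real 73, the real one among them, and the highest other split called 2005. That split exchanges all 3 camptothecin pairs, which turns the contrast into the sum of both knockdown effects, a structure of the samples. The other 3, with 131, 117 and 79, exchange 2 camptothecin pairs and keep all vehicle labels, so they hold knockdown effects too, and this count does not settle whether chance can be excluded. For the 4 pairwise comparisons 10 splits are too few for a share under 0.05: only 1 of 10, the real one, called as many genes, with real and highest other counts of 1339 and 0 for knockdown under vehicle, 736 and 0 for knockdown under camptothecin, 3832 and 1 for camptothecin in control cells and 3169 and 0 for camptothecin in knockdown cells.

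Probes without a gene symbol were outside the tests of genes, and among 1506 that passed the detection filter, calls numbered 236 for knockdown under vehicle, 132 for knockdown under camptothecin, 591 for camptothecin in control cells, 515 for camptothecin in knockdown cells and 16 for the interaction, a signal in data not used above. With groups of 3 arrays no test for single outlying arrays was made.

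Of the calls in knockdown cells under vehicle, 72.7% were higher, against 51.5% among genes detected on all 12 arrays. That filter removed 665 higher calls, of which 662 were undetected on a control vehicle array, so it takes out genes that start below detection and decides nothing. Since brightness moves with knockdown status, array brightness and a difference between the cell states cannot be told apart here.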

How the results depend on the processing

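Median scaling over detected probes and the brightness covariate were chosen after seeing the data, as was the choice of lists with named members. Among 218 values of list members left unnamed by it (167 past the threshold), 18 turned direction relative to the median shift under the 2 median scalings, in 9 genes and comparisons. Of these 8 were in knockdown under vehicle (PHLDA3, EGR1, NFKB2, IRF9, HLA-C, IFT57, CLK4 and CD68), and CD68 also turned in the interaction.

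Counts follow in the order knockdown under vehicle (1339 genes, 6 lists), knockdown under camptothecin (736, 9), camptothecin in control cells (3832, 11), camptothecin in knockdown cells (3169, 8) and interaction (73, 7). Median scaling gave 7290 and 5600 genes for the first 2, 1946 for camptothecin in knockdown cells and 24 for the interaction, with median shifts of all genes of 1.43 and 0.87 in the knockdown comparisons, 4 lists for knockdown under camptothecin and 4 for the interaction, and 5216 (from 312) and 969 (from 2441) genes called in the same direction for the knockdown and the camptothecin effects. Among the 4504 genes detected on all arrays, fewer genes being tested, knockdown under vehicle gave 861 genes, camptothecin in control cells 2488 and the interaction 24, and lists numbered 1, 1 and 5 in the first 3 comparisons. With only the arrays compared, the first 4 comparisons gave 544, 1044, 2707 and 4355 genes, and with array weights 1024, 1211, 3195 and 4339. Both settings reversed which of the knockdown comparisons, and which of the camptothecin comparisons, called more genes. The sizes of these counts therefore do not rank the comparisons. With an estimated correlation 2, 0 and 4 lists were called in the first 3 comparisons and 0 in the interaction, and with fry 14, 15, 22 and 19 in the first 4. Median scaling over detected probes gave 2905 genes for knockdown under vehicle and 111 for the interaction. The brightness covariate gave 18, 96 and 24 genes for knockdown under vehicle, knockdown under camptothecin and the interaction. Its median standard error for knockdown under vehicle was 0.38 against 0.19, and GSDMA went from -1.85 to 0.10 there. The cause was not tested for these changes.

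The replicate numbers share no more than a label: correlations of same-numbered deviations were -0.208 to 0.125, with 1 of 18 over 0.1, and 3 of 12 arrays correlated best with their own number. With the replicate block the interaction gave 35 genes, and no other count moved by over 1.5 times. The block also ended the list call of the unfolded protein response for knockdown under camptothecin (adjusted p = 0.0509). The calls of kidney markers for camptothecin in knockdown cells (0.0588) and of p53 targets in the interaction (0.0621) ended too.

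Leaving out each array gave 683 to 1810 genes for knockdown under vehicle (747 without knockdown vehicle replicate 2), 371 to 1181 for knockdown under camptothecin, 3346 to 3868 and 2539 to 3675 for camptothecin in control and knockdown cells and 15 to 277 for the interaction. Lists ranged from 5 to 6, 5 to 11, 10 to 12, 7 to 8 and 6 to 7, with 5 for knockdown under camptothecin without control camptothecin replicate 1 and without knockdown camptothecin replicate 3. Genes called in the same direction ranged from 190 to 367 and from 1978 to 2656, and SPAG4 from -0.03 to 0.07 under vehicle and from -0.20 to 0.04 under camptothecin. Among alternatives other than leaving out arrays, 115 results that answer a comparison stayed (counts within 1.5 times) and 30 did not, and of the values of single genes 2098 kept direction and side of the threshold, 146 fell short of it, 35 newly passed and 1 reversed. Under the 2 median scalings, direction in this tally was relative to the median shift of all genes, while the adjusted p tested the unshifted change. The tally therefore does not show that unshifted directions held there. The tally also counts no background correction and the deposited processed values apart, although these are in effect the same values. Genes near background, SPAG4 among them, are limited by signal over background.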

Other observations

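The window tests for neighbouring genes (with the only window size that was run), the detection patterns and the genes named with them were chosen only after the result was seen. Among 71 genes of chromosome 8 between MSRA and DDHD2, knockdown cells had lower levels of 33 and higher levels of 4 under vehicle, and 38 and 5 under camptothecin. The mitophagy receptor BNIP3L was at -0.83 (adjusted p = 0.00627) under vehicle and -1.33 (adjusted p = 0.000608) under camptothecin, and the neurofilament NEFL at -1.29 (adjusted p = 0.00428) and -1.77 (adjusted p = 0.000932). Its neighbour NEFM went the other way, at 1.13 (adjusted p = 0.00223) and 1.03 (adjusted p = 0.00502). Near the MSRA end, PINX1 (1.33 and 0.88), MTMR9 (1.05 and 1.13) and LONRF1 (0.54 and 0.63) were also higher and past the threshold under both treatments. The probes of these genes were detected on all 6 knockdown arrays and on no control array, so the sizes are uncertain. Knockdown arrays were also brighter. The helicase WRN was at -0.67 under vehicle (adjusted p = 0.0221) and -0.35 under camptothecin (adjusted p = 0.243). In windows of 25 genes, 51 passed the threshold under vehicle, 47 of them in this stretch and 4 on chromosome 22. Under camptothecin 98 windows passed, 80 lower, of which 53 were on chromosome 8, 24 on chromosome 22 and the rest on chromosomes 10 and 17, and 18 higher, all on chromosomes 7 and 21. Windows also passed for camptothecin against vehicle within the same cells, 35 in control and 36 in knockdown cells, so windows that pass do not by themselves point to copy number. The stretch itself had medians of 0.07 and -0.05 there.

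Probes detected on all 6 control arrays and 0 knockdown arrays numbered 4, those of HSPA1A, C19orf12 and LOC105379362 and 1 without a symbol, all over 2-fold lower. Probes detected on all 6 knockdown arrays and 0 control arrays numbered 83, 68 with a gene symbol and 13 over 2-fold higher, among them those of ZNF35, LRRC26 and ZSCAN18. Knockdown arrays were brighter and detected more probes (11750 and 12458 against 8509 and 11059 on average), so this imbalance does not by itself separate the cell states.

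Most but not all genes of the chromosome 8 stretch shifted down in knockdown cells, 53 of 71 under vehicle and 59 under camptothecin. The stretch's median log2 fold change was -0.51 under vehicle and -0.82 under camptothecin against 0.15 and 0.06 for other genes. The stretch lay below all genes by 0.64, 0.61 and 0.64 on the knockdown vehicle arrays and by 0.90, 0.82 and 0.85 on the knockdown camptothecin arrays. A brightness effect that acts through mean signal alone is argued against, since 51 windows under vehicle still passed when genes were exchanged only with genes of similar mean signal. The threshold was 0.384 with free exchange and 0.385 with this exchange. Other effects of array brightness on this stretch were not tested. Of these 51 windows 98.0% passed with the same sign under camptothecin, on other arrays. The windows overlap and 47 of them lie in this stretch, so the share is not a rate over independent regions. A copy number difference between the knockdown and control cells may be involved, but any lasting difference between these cells would persist in the same way. DNA was not measured, and an effect of the knockdown itself on this stretch stays open and untested.

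Without those 71 genes, the lists called numbered 8, 9, 13, 7 and 6 in the order of comparisons given above. Knockdown under vehicle gained neuronal markers (adjusted p = 0.0149, with an estimated correlation adjusted p = 0.120) and p53 target genes (0.0495 and 0.205). The stretch was chosen for its low levels in this comparison, so its removal favours higher lists and these gains are no further support. It took TNFRSF10B (-0.80) from the p53 list, and NEFL (-1.29) and NEFM (1.13) from the neuronal list. Camptothecin in control cells gained neuronal markers (0.0187 and 0.0768) and RNA polymerase II elongation and splicing (0.0458 and 0.156). None of these held with an estimated correlation. Camptothecin in knockdown cells lost kidney epithelial markers (0.0504), and the interaction lost p53 target genes (0.0679).

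Camptothecin lowered long genes more than short ones. Spearman's rho of the log2 fold change with gene length was -0.324 in control and -0.378 in knockdown cells (8252 genes, which are not independent; permutation p = 0.001, the smallest that 1000 permutations give). Genes of at least 200 kb (396) had medians of -0.62 and -0.82, genes under 5 kb (943) 0.38 and 0.26. Array brightness is argued against by a rho of 0.0614 for knockdown under vehicle, and signal level by a rho of -0.425, -0.415 and -0.239 in control cells for genes of low, middle and high mean signal. That trapped topoisomerase I hinders the transcription of long genes is a hypothesis drawn from the same data. These values show the link with gene length and do not test the trapping. Leaving out each array gave a rho of -0.353 to -0.280 in control and -0.392 to -0.364 in knockdown cells.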
